A study of Mus musculus with 40 samples.

How the data were processed

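RNA of mouse subcutaneous white adipose tissue was profiled in 40 samples of 5 groups with 8 samples each: ND, HFD, HFD with semaglutide, HFD with tirzepatide and the diet switch from HFD to ND. Per the labels' protocols, RNA was extracted with Nucleozol, libraries were made with the LexoGen QuantSeq kit, which counts the ends of transcripts, and were sequenced on an Illumina HiSeq. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program and the annotation are not given in the sources used here. The authors deposited a table of counts per gene symbol. The authors also deposited a table of normalized signal per gene. Dividing the counts by 1 factor per library gives the normalized table (largest relative spread of the ratio 1.2e-09), so it holds no second measurement and the counts were used. The count table has 16 further columns that match no sample of the series, and they were used in nothing.

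The table lists 34843 symbols, of which 630 had no count in any of the 40 libraries. Totals ran from 2115471 to 7445548 counts per library, with a median of 3765000. The edgeR function filterByExpr with default settings kept 15807 genes, which hold 99.39% of the counts. GENCODE M21 gave coordinates for 31404 symbols and for 15104 of the tested genes (95.6%). The smallest chi-square per degree of freedom between 2 libraries of a group was 4.21, so no 2 libraries are copies of one another.

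Counts were normalized with TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 with robust dispersions, with the 40 libraries in 1 fit and 1 mean per group. The 10 comparisons were HFD against ND, each treatment against HFD and against ND, and the 3 treatments against each other. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison were called. At this depth the typical gene's spread shows in the SE printed beside each log2 fold change. The 36 fixed gene lists were tested with camera of limma 3.58.1 with an estimated correlation between genes, on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. Members were counted by the calls over all genes and by p-values adjusted over the list alone. Levels are log2 CPM. Group values are given with SD over 8 libraries, and differences of list scores with SE over the libraries compared. The SE of a log2 fold change is its size over the root of the F statistic. It thus rests on the spread in all libraries of the fit.

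Named genes followed a fixed rule: 24 marker genes, the 8 largest changes in each direction per comparison against HFD or ND (6 in the direct ones) among called genes without overlap of one group with the other's median and with a mean of at least 2 log2 CPM, and up to 4 members with the smallest adjusted p of each list described. Genes called on HFD were sorted by their calls against HFD and ND in each treatment. The recovery share is the median movement of HFD genes from the HFD mean toward ND in a treatment, divided by the median distance from HFD to ND, in percent. Its genes were called in the libraries with odd or even numbers and measured in the others, with 1000 bootstrap draws of libraries and exact permutation of the scores of the 16 libraries compared. Agreement between treatments is Pearson's r of fold changes, set against 20 simulations in which no treatment differs from HFD and against fits that split the HFD libraries.

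Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a stricter filter (10 counts in 8 libraries), only the groups compared, the replicate number as a block, limma-voom with quality weights, a threshold of 1.5-fold, each library left out in turn, and for lists a preset correlation of 0.01 and fry. Further alternatives, chosen after seeing the data, left out 4 libraries with high B cell genes, 11 with high muscle genes, or 3 diet-switch libraries. The recovery share was also taken without the muscle-high libraries and without genes whose correlation with the muscle score within groups is above 0.5. Others corrected for GC content and transcript length, added the first axis of variation within groups, or dropped 43 tested ribosomal, mitochondrial and hemoglobin genes. The axis was found from the spread within groups, but libraries were scored on it with group differences kept. As a covariate it can thus also remove part of a difference between groups. GC content and length were means over a gene's whole transcripts, not over the ends that QuantSeq counts. The groups, comparisons, lists, named-gene rule and first set of alternatives were fixed before the data were examined. For each comparison 100 splits of its 16 libraries were counted.

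The procedure was tested on simulated data with 15560 genes, of which 200 changed between HFD and ND. It called 10 of 67 genes at 1.5-fold (14.9%), 41 of 67 at 2-fold (61.2%) and 63 of 66 at 4-fold (95.5%), and 4 unchanged genes. Recovery shares simulated at 0, 50 and 100% were estimated at 2.22, 48.4 and 98.1%. A list of 34 genes all raised 2-fold had camera's adjusted p of 1.29e-19, and 0 of 35 unchanged lists passed. Genes were drawn independently there, so this does not show the power for lists of correlated genes. R was 4.3.3, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.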

Results

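The series holds RNA profiles of mouse subcutaneous white adipose tissue (sWAT), the fat depot under the skin, from 5 groups of 8 samples. The groups were normal diet (ND), high-fat diet (HFD), HFD with semaglutide, HFD with tirzepatide, and a diet switch from HFD back to ND. Semaglutide is a lipidated peptide that activates the receptor of glucagon-like peptide 1, and tirzepatide is a lipidated peptide that activates that receptor and the receptor of glucose-dependent insulinotropic polypeptide (GIP). The stated question was which genes stay deregulated and which are restored by these incretin analogs. Lexogen QuantSeq libraries gave 2115471 to 7445548 counts per sample (median 3765000), with 19900 to 23774 genes detected. Totals averaged 3753000 ± 536400 (SD, n = 8) in ND, 4077000 ± 840500 in HFD, 3712000 ± 386400 with semaglutide, 4080000 ± 1636000 with tirzepatide and 3751000 ± 584500 after the switch. The labels give no dose, treatment time, collection time or sex, and do not say what the diet-switch mice had received before the switch. The series title sets a dietary intervention after incretin treatment, so these mice may have had a drug first, and each comparison with this group would then have another meaning. They do not say whether samples of a group are separate animals beyond calling them samples, so p-values measure the spread between these samples.

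Markers of other tissues varied between libraries of one group. The mean level of B cell genes was 6.87 log2 CPM (counts scaled to library size) in ND library 5 and 6.99, 6.27 and 5.74 in semaglutide libraries 1, 3 and 8. The group means were 2.73 ± 1.74 in ND (SD, n = 8), 2.55 ± 0.647 in HFD, 3.74 ± 2.19 with semaglutide, 2.23 ± 0.366 with tirzepatide and 2.39 ± 0.516 after the switch. Skeletal muscle genes averaged 4.42 ± 2.44 in ND, 2.38 ± 1.35 in HFD, 2.43 ± 1.36 with semaglutide, 4.99 ± 2.19 with tirzepatide and 4.26 ± 2.28 after the switch. They lay above 5 in 11 libraries, which were ND 6 and 8, HFD 4, tirzepatide 1, 2, 4, 5 and 7, and diet switch 1, 3 and 6. Diet-switch libraries 3, 4 and 7 lay at 80.6, 73.1 and 62.1 on the first axis of variation within groups, where the next library, tirzepatide 8, lay at 36.0. Group means on this axis were -16.5 ± 19.4 in ND (SD, n = 8), -17.8 ± 19.0 in HFD and -7.9 ± 14.6 with semaglutide. They were 15.2 ± 19.0 with tirzepatide and 27.0 ± 42.4 after the switch. Where the axis is used as a covariate below, it can thus also remove part of a group difference. 18S RNA took 4.74 ± 0.994% of counts after the switch (SD, n = 8), against 7.41 ± 0.928 in ND, 7.52 ± 1.00 in HFD, 6.42 ± 1.63 with semaglutide and 7.09 ± 2.54 with tirzepatide. Mitochondrial counts were 15.2 ± 3.70% after the switch, 14.8 ± 2.10 in ND, 11.8 ± 2.10 in HFD, 10.9 ± 1.77 with semaglutide and 11.7 ± 3.20 with tirzepatide. Library numbers run by group, so library order and group cannot be told apart.

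**Figure D1:**
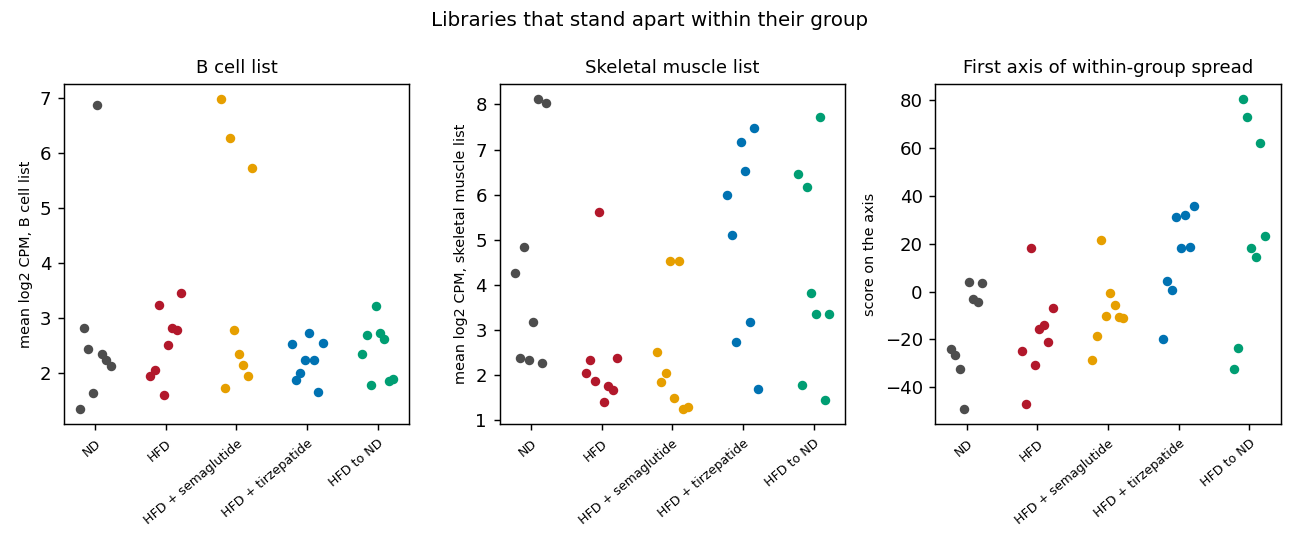
Each point is 1 of the 40 libraries, by group: mean log2 CPM of the B cell and skeletal muscle lists, and the position on the first axis of variation within groups. ND 5 and semaglutide 1, 3 and 8 stand out for B cell genes, and diet-switch 3, 4 and 7 on the axis.

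On HFD 4 enzymes of fatty acid synthesis were far below ND. Log2 fold changes with their SE (n = 8 per group) were -2.71 ± 0.27 for Acaca, acetyl-CoA carboxylase, -2.29 ± 0.35 for Fasn, fatty acid synthase, -2.15 ± 0.34 for Acly, ATP citrate lyase, and -1.80 ± 0.21 for Scd1, stearoyl-CoA desaturase. Fasn went from 4878 ± 1447 CPM in ND to 1000 ± 182 in HFD (SD), with 8 of 8 HFD libraries below the ND median (edgeR adjusted p = 3.45e-05). Genes tied to growing fat rose: Mest 2.17 ± 0.46, an imprinted gene that marks fat expansion, Sfrp5 1.82 ± 0.39, a secreted Wnt inhibitor, and Lep 1.40 ± 0.29, the hormone leptin. The inflammation-linked Ubd, a ubiquitin-like modifier, rose by 4.80 ± 0.48. Cyp2f2, a monooxygenase of xenobiotic metabolism, fell by 4.98 ± 0.52, and genes of the major urinary proteins (Mup) fell as well.

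Among the genes tested, 447 rose and 265 fell on HFD (712 in all; edgeR adjusted p under 0.05). In the lipogenesis list, of the 25 measured, 13 fell and 12 did not pass; 1 rose and 14 fell adjusted over the list alone, and camera's adjusted p was 0.102 with an estimated correlation. In the adipose expansion list, of the 7 measured, 4 rose and 3 did not pass; 6 rose adjusted over the list alone, and camera's adjusted p was 0.151 with an estimated correlation. For lipid-associated macrophages, of the 18 measured, 7 rose and 11 did not pass; 10 rose adjusted over the list alone, and camera's adjusted p was 0.102 with an estimated correlation; Trem2, a lipid receptor of these cells, rose by 1.75 ± 0.45, Itgax, an integrin of adipose macrophages and dendritic cells, by 1.41 ± 0.30 and Atp6v0d2, a lysosomal proton pump subunit, by 2.28 ± 0.53. In the list of inflammatory mediators, of the 14 measured, 3 rose and 11 did not pass; 5 rose adjusted over the list alone, and camera's adjusted p was 0.102 with an estimated correlation; Il1rn, an interleukin receptor antagonist, rose by 2.27 ± 0.51, while Ccl2, a monocyte attractant, stood at 1.33 ± 0.47. In the fatty acid oxidation list, of the 18 measured, 6 rose and 12 did not pass; 10 rose adjusted over the list alone, and camera's adjusted p was 0.151 with an estimated correlation, with Cpt1a, the mitochondrial carnitine acyltransferase, at 0.90 ± 0.16 and Acadm, an acyl-CoA dehydrogenase, at 0.88 ± 0.19.

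For lipolysis and lipid droplet genes, of the 17 measured, 6 rose, 1 fell and 10 did not pass; 9 rose and 2 fell adjusted over the list alone, and camera's adjusted p was 0.226 with an estimated correlation. The droplet proteins Plin5 (1.66 ± 0.27) and Cidec (1.11 ± 0.17) rose, and Adrb3, the beta-adrenergic receptor of adipocytes, fell by 2.15 ± 0.35. In the adipocyte identity list, of the 18 measured, 1 rose, 3 fell and 14 did not pass; 1 rose and 4 fell adjusted over the list alone, and camera's adjusted p was 0.840 with an estimated correlation; the complement protease Cfd (adipsin) fell by 2.81 ± 0.35, and the adipocyte hormone Adipoq stood at -0.01 ± 0.17. Slc2a4, the insulin-responsive glucose transporter, fell by 0.58 ± 0.15 (adjusted p = 0.0140), a call lost without ND library 8 (edgeR adjusted p = 0.0506). The 17 Mup genes tested lay between -3.27 and -2.94, but they are near-identical copies whose counts may be split between them, so single members are uncertain. Gipr, the GIP receptor, stood at 1.83 ± 0.56 (adjusted p = 0.0463), with the call lost (adjusted p up to 0.11) on leaving out any single library other than ND 1, HFD 4 and 7, semaglutide 1, 6 and 8, tirzepatide 1, 3 and 4, and diet switch 3, 4, 5, 7 and 8. The Gipr call also ended (adjusted p in brackets) without the filter (0.0647), with the replicate block (0.0839) and with limma-voom weights, at 1.43 (0.19). Its level was low, at 0 to 1.76 CPM in ND libraries and 0 to 4.90 in HFD ones. Glp1r was near the floor, with 24 counts over the 8 ND libraries, 3 in HFD, 8 with semaglutide, 20 with tirzepatide and 15 after the switch, too few for a test. In the muscle list, of the 14 measured, 3 fell and 11 did not pass; 13 fell adjusted over the list alone, and camera's adjusted p was 0.540 with an estimated correlation, beside the muscle levels given above. With limma-voom quality weights 1289 genes passed. Without the 11 muscle-high libraries 4 calls end with fewer samples in the fit, at log2 fold changes (adjusted p in brackets) of Trem2 1.69 ± 0.51 (0.0692), Atp6v0d2 2.10 ± 0.66 (0.0830), Slc2a4 -0.54 ± 0.17 (0.0856) and Gipr 1.83 ± 0.63 (0.113).

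**Figure D2:**
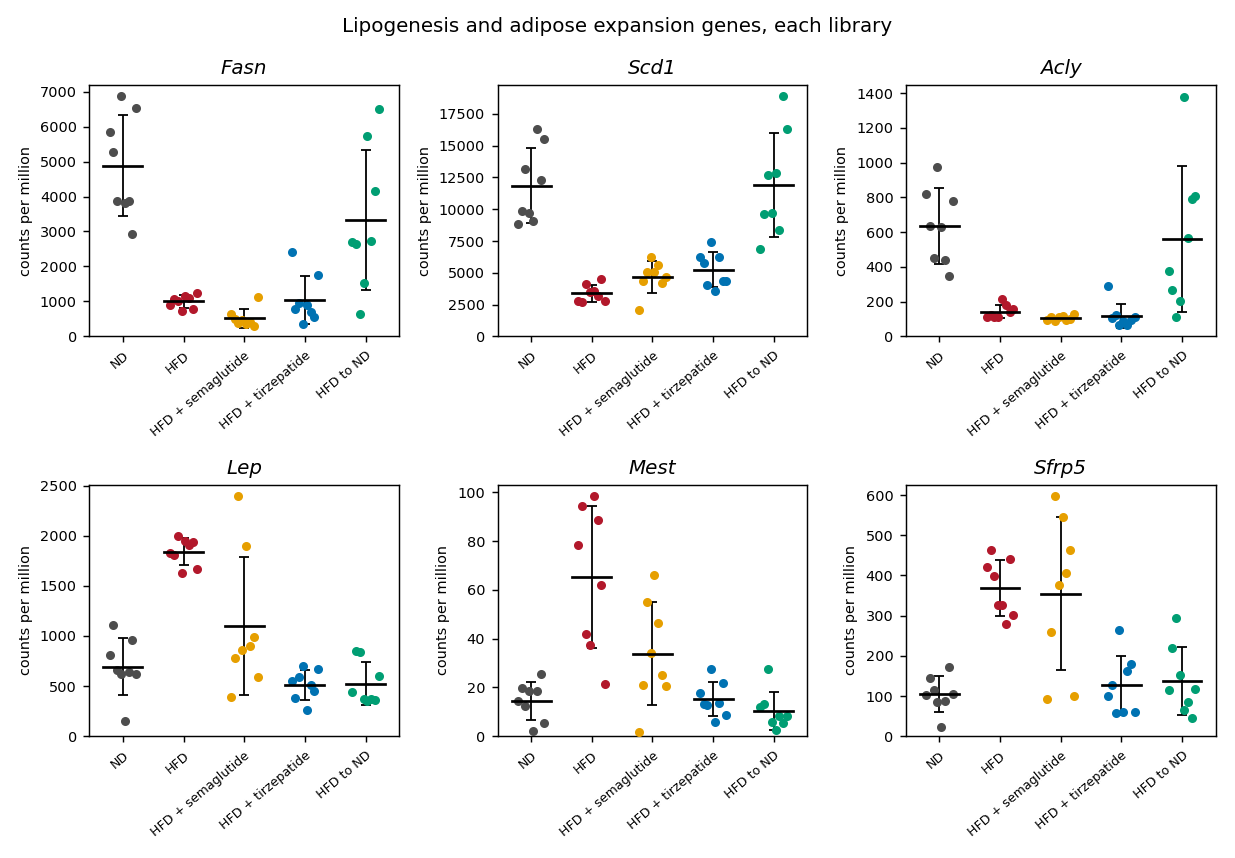
CPM of 6 named genes in each library (points) with group means and SD (bars), n = 8 per group. Mean Fasn, Acly and Scd1 are lower in HFD and both drug groups than in ND and the diet switch, and mean Lep, Mest and Sfrp5 are higher in HFD than in ND.

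Semaglutide was compared with HFD to ask what it changes on continued HFD. Some sterol synthesis genes fell, with log2 fold changes (SE, n = 8 per group) of -1.55 ± 0.29 for Lss, lanosterol synthase, -1.41 ± 0.27 for Nsdhl and -1.07 ± 0.19 for Pmvk, enzymes of the same pathway. Genes raised on HFD that fell included Oxtr -2.27 ± 0.44, the oxytocin receptor, and Ubd -2.05 ± 0.40. Cfd rose by 2.10 ± 0.34 (edgeR adjusted p = 1.38e-04, above the HFD median in 8 of 8 libraries) and Gpx3, a secreted glutathione peroxidase, by 1.76 ± 0.24. Of the genes of fat expansion Lep -0.74 ± 0.29, Mest -0.94 ± 0.44 and Sfrp5 -0.06 ± 0.38 did not pass, nor did Fasn -0.94 ± 0.34 or Slc2a4 -0.16 ± 0.15. Lep passes without semaglutide 3 (-1.01) and Fasn without semaglutide 8 (-1.21).

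In all 241 genes rose and 415 fell. In the cholesterol list, of the 21 measured, 8 fell and 13 did not pass; 12 fell adjusted over the list alone, and camera's adjusted p was 0.205 with an estimated correlation. In the lipogenesis list, of the 25 measured, 6 fell, 1 rose and 18 did not pass; 2 rose and 11 fell adjusted over the list alone, and camera's adjusted p was 0.335 with an estimated correlation, with Slc25a1, the mitochondrial citrate carrier, at -1.69 ± 0.30 and Me1, malic enzyme, at -1.14 ± 0.23. In the matrix list, of the 31 measured, 5 fell, 1 rose and 25 did not pass; 1 rose and 11 fell adjusted over the list alone, and camera's adjusted p was 0.205 with an estimated correlation; the basement membrane collagen Col4a2 (-1.02 ± 0.17), elastin (Eln, -1.11 ± 0.21) and Sparc (-0.87 ± 0.20) fell. In the brown and beige adipocyte list, of the 15 measured, 5 fell and 10 did not pass; 1 rose and 5 fell adjusted over the list alone, and camera's adjusted p was 0.205 with an estimated correlation; Dio2, which activates thyroid hormone, fell by 3.40 ± 0.54, and Ucp1, the uncoupling protein, stood at 2.12 ± 1.42 and did not pass, a value that rests on semaglutide 8, without which it is -1.05. In the clock list, of the 15 measured, 5 rose, 1 fell and 9 did not pass; 8 rose and 1 fell adjusted over the list alone, and camera's adjusted p was 0.205 with an estimated correlation, with Per2 1.03 ± 0.24 and Hlf 1.06 ± 0.19. In the B cell list, of the 5 measured, 3 rose and 2 did not pass; 4 rose adjusted over the list alone, and camera's adjusted p was 0.603 with an estimated correlation, beside the B cell levels of semaglutide libraries 1, 3 and 8. Without those 3 libraries and ND 5, 412 genes passed in place of 656. Without HFD library 5 the count was 437, with DESeq2 1023, with limma-voom weights 1263 and with only these 2 groups in the fit 1013.

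Against HFD tirzepatide gave 1548 genes up and 1698 down, with Oxtr and Ubd among the lower ones. Log2 fold changes (SE, n = 8 per group) were -4.03 ± 0.49 for Oxtr and -3.21 ± 0.43 for Ubd. Expansion genes that fell were Lep -1.84 ± 0.30, Mest -2.13 ± 0.46, Sfrp5 -1.55 ± 0.39 and Npr3 -1.07 ± 0.31, the clearance receptor of natriuretic peptides. Lep went from 1839 ± 134 CPM to 513 ± 148 (SD; edgeR adjusted p = 2.29e-05, below the HFD median in 8 of 8 libraries). Slc2a4 rose by 0.78 ± 0.15, Cfd by 3.13 ± 0.35 and Cyp2f2 by 3.43 ± 0.51.

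In the adipose expansion list, of the 7 measured, 5 fell, 1 rose and 1 did not pass; 1 rose and 5 fell adjusted over the list alone, and camera's adjusted p was 0.653 with an estimated correlation. In the list of inflammatory mediators, of the 14 measured, 6 fell and 8 did not pass; 1 rose and 6 fell adjusted over the list alone, and camera's adjusted p was 0.438 with an estimated correlation, with Ccl2 -1.62 ± 0.47, Nos2 -2.30 ± 0.45, the inducible nitric oxide synthase, and Saa3 -2.14 ± 0.54, a serum amyloid. Lipogenesis genes went both ways: of the 25 measured, 10 fell, 6 rose and 9 did not pass; 6 rose and 11 fell adjusted over the list alone, and camera's adjusted p was 0.823 with an estimated correlation. Me1 (-1.29 ± 0.23), Scd2 (-1.55 ± 0.29) and Dgat2, an enzyme of triglyceride synthesis (-1.48 ± 0.27), fell, Fads1, a fatty acid desaturase, rose by 0.98 ± 0.17, and Fasn (0.07 ± 0.34) and Acly (-0.29 ± 0.33) did not pass. In the cholesterol list, of the 21 measured, 10 fell and 11 did not pass; 11 fell adjusted over the list alone, and camera's adjusted p was 0.438 with an estimated correlation, with Lss -1.79 ± 0.29 and Nsdhl -1.92 ± 0.28. In the matrix list, of the 31 measured, 12 fell, 1 rose and 18 did not pass; 2 rose and 17 fell adjusted over the list alone, and camera's adjusted p was 0.653 with an estimated correlation, with Col4a2 -1.15 ± 0.17 and Loxl2, a lysyl oxidase, at -1.29 ± 0.21. In the skeletal muscle list, of the 14 measured, 5 rose and 9 did not pass; 10 rose adjusted over the list alone, and camera's adjusted p was 0.653 with an estimated correlation, beside muscle levels above 5 in 5 of the 8 tirzepatide libraries and 1 HFD library; Myh1, a myosin of fast muscle, stood at 4.74 ± 1.23. Without the 11 muscle-high libraries 1145 genes passed in place of 3246, with fewer samples in the fit. Not among them were (adjusted p in brackets) Ccl2 -1.49 ± 0.53 (0.0797), Nos2 -1.73 ± 0.56 (0.0558), Saa3 -1.37 ± 0.71 (0.255), Npr3 -1.29 ± 0.47 (0.0975) and Myh1 0.82 ± 1.17 (0.734). With the axis of variation as a covariate it was 1885, where Ccl2 stood at -1.43 ± 0.53 and did not pass (0.0704), and Myh1 did not pass with limma-voom weights (0.146).

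After the diet switch 4 lipogenic enzymes were above their HFD level. Log2 fold changes (SE, n = 8 per group) were 2.32 ± 0.27 for Acaca, 1.97 ± 0.34 for Acly, 1.81 ± 0.21 for Scd1 and 1.74 ± 0.35 for Fasn, and Fasn lay above the HFD median in 7 of 8 libraries (edgeR adjusted p = 3.85e-04). Expansion genes that fell were Mest -2.62 ± 0.47, Lep -1.81 ± 0.30 and Sfrp5 -1.43 ± 0.39. Itgax fell by 1.52 ± 0.30 and Oxtr by 4.15 ± 0.49. Pck1, the enzyme of glycerol synthesis in fat, rose by 1.38 ± 0.27, Slc2a4 by 0.59 ± 0.15 and Insr, the insulin receptor, by 1.09 ± 0.22.

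In all 2030 genes rose and 1729 fell. In the lipogenesis list, of the 25 measured, 9 rose, 5 fell and 11 did not pass; 11 rose and 5 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation. In the adipocyte identity list, of the 18 measured, 8 rose and 10 did not pass; 8 rose and 1 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation. In the lipid-associated macrophage list, of the 18 measured, 6 fell, 1 rose and 11 did not pass; 1 rose and 7 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation, and Trem2 stood at -0.70 ± 0.43. In the cholesterol list, of the 21 measured, 10 fell and 11 did not pass; 14 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation, with Hmgcs1, an early enzyme of the pathway, at -1.18 ± 0.23. In the interferon list, of the 19 measured, 6 rose, 1 fell and 12 did not pass; 7 rose and 1 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation, with Ifi44 1.98 ± 0.46. The 17 Mup genes rose, by 2.48 to 2.88, with the uncertainty named above. Across 10288 protein-coding genes, which are not independent replicates, the fold change correlated with GC content at r = -0.323, and the share of 18S RNA was lower after the switch, as given above. After the correction for GC content and length 3313 genes passed, and 3721 with ribosomal, mitochondrial and hemoglobin genes left out. Without diet-switch libraries 3, 4 and 7 the count of genes was 1148 in place of 3759, with Insr at 0.63 ± 0.22 no longer among them (adjusted p = 0.0682). With the axis of variation as a covariate it was 801, where Ifi44 stood at 1.14 ± 0.46 (adjusted p = 0.153) and Insr at 0.31 ± 0.18 (0.343).

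**Figure D3:**
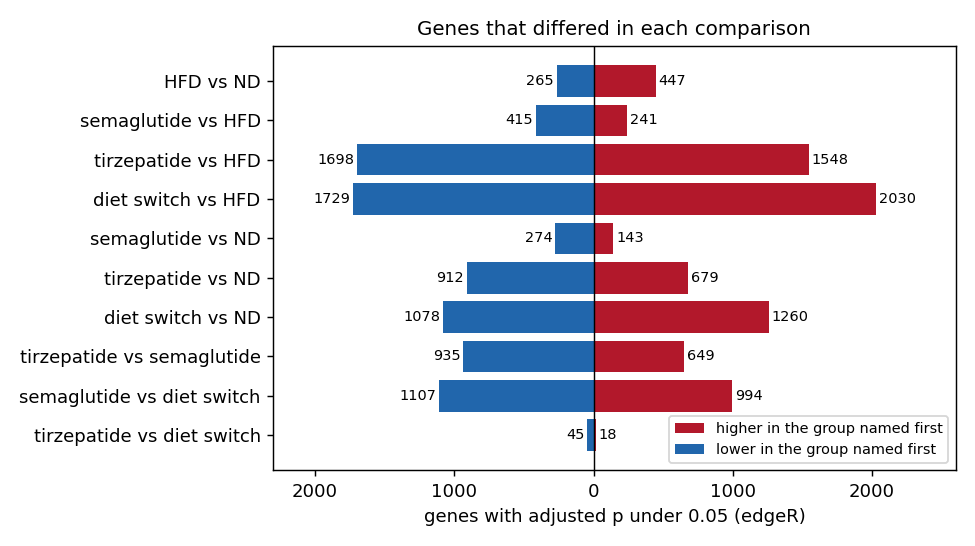
Bars give the number of genes called higher (up) and lower (down) in each of the 10 comparisons (edgeR adjusted p under 0.05). The diet switch against HFD has the most, 3759, and tirzepatide against the diet switch the fewest, 63.

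Comparisons with ND asked which genes stayed away from the lean level. With semaglutide the lipogenesis genes were below ND: Fasn -3.22 ± 0.37, Acaca -2.62 ± 0.27, Acly -2.59 ± 0.35 and Tkt -2.06 ± 0.25, a pentose phosphate enzyme (log2, SE, n = 8 per group). Fasn lay below the ND median in 8 of 8 libraries (edgeR adjusted p = 2.87e-07). In the list, of the 25 measured, 18 fell and 7 did not pass; 20 fell adjusted over the list alone, and camera's adjusted p was 9.1e-04 with an estimated correlation, so this list passed. The clock list passed as well: of the 15 measured, 8 rose, 2 fell and 5 did not pass; 8 rose and 3 fell adjusted over the list alone, and camera's adjusted p was 0.0148 with an estimated correlation. Per2 and Per3, repressors of the clock loop, rose by 2.11 ± 0.26 and 1.49 ± 0.20, and Nr1d2, a nuclear receptor of the clock, by 1.48 ± 0.20. In the cholesterol list, of the 21 measured, 9 fell and 12 did not pass; 12 fell adjusted over the list alone, and camera's adjusted p was 0.113 with an estimated correlation. Sfrp5 was above ND by 1.76 ± 0.39, Slc2a4 below it at -0.74 ± 0.15, and Lep stood at 0.66 ± 0.29. In all 143 genes were higher and 274 lower than in ND. The count of 417 became 267 without the filter, 952 with limma-voom weights, and 264, 256, 853 and 272 without ND 1, ND 4, ND 5 and semaglutide 3.

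With tirzepatide 679 genes were higher and 912 lower than in ND. In the lipogenesis list, of the 25 measured, 18 fell and 7 did not pass; 21 fell adjusted over the list alone, and camera's adjusted p was 0.0318 with an estimated correlation, with Elovl6 -2.82 ± 0.43, an elongase, Acss2 -2.44 ± 0.32, an acetyl-CoA synthetase, Acly -2.44 ± 0.34 and Fasn -2.22 ± 0.35. In the clock list, of the 15 measured, 6 rose, 4 fell and 5 did not pass; 11 rose and 4 fell adjusted over the list alone, and camera's adjusted p was 0.0469 with an estimated correlation; Per2 rose by 2.37 ± 0.26 and Tef by 1.47 ± 0.19, and Arntl, the activator of the loop, fell by 2.58 ± 0.38. This clock result rose to camera's adjusted p of 0.0968 with the replicate block and 0.107 with the correction for GC content and length, each with an estimated correlation. In the lipid-associated macrophage list, of the 18 measured, 4 rose and 14 did not pass; 7 rose adjusted over the list alone, and camera's adjusted p was 0.844 with an estimated correlation, with Gpnmb 1.61 ± 0.33 and Trem2 1.56 ± 0.45. Gipr was above ND by 2.09 ± 0.56 (adjusted p = 0.0127), at low levels of 1.20 to 4.93 CPM with tirzepatide and 0 to 1.76 in ND. Lep (-0.44 ± 0.29), Mest (0.04 ± 0.47), Sfrp5 (0.28 ± 0.38) and Slc2a4 (0.20 ± 0.15) did not pass. The count of 1591 became 2451 with limma-voom weights, 332 without muscle-high libraries, 448 with the axis as a covariate, and 1046 and 1054 without ND 4 and tirzepatide 4. Without muscle-high libraries, with fewer samples in the fit, Gpnmb 1.27 ± 0.51 (0.183), Trem2 1.21 ± 0.61 (0.300) and Gipr 1.82 ± 0.73 (0.172) did not pass (adjusted p in brackets), nor did Gipr 1.80 ± 0.61 (0.0932) with the axis or Trem2 1.56 ± 0.47 (0.0550) without the filter.

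After the diet switch Fasn -0.55 ± 0.34, Acly -0.18 ± 0.32 and Scd1 0.01 ± 0.20 did not pass against ND, while in the list, of the 25 measured, 7 fell and 18 did not pass; 8 fell adjusted over the list alone, and camera's adjusted p was 0.852 with an estimated correlation, with Dgat2 -1.23 ± 0.27. In the cholesterol list, of the 21 measured, 10 fell and 11 did not pass; 14 fell adjusted over the list alone, and camera's adjusted p was 0.319 with an estimated correlation, with Mvd -1.27 ± 0.28. In the clock list, of the 15 measured, 8 rose, 3 fell and 4 did not pass; 8 rose and 3 fell adjusted over the list alone, and camera's adjusted p was 0.319 with an estimated correlation, with Per2 2.31 ± 0.26 and Arntl -1.99 ± 0.36. In the matrix list, of the 31 measured, 8 rose, 3 fell and 20 did not pass; 8 rose and 5 fell adjusted over the list alone, and camera's adjusted p was 0.940 with an estimated correlation; Thbs1, a matrix glycoprotein, rose by 1.97 ± 0.40 and the collagen Col6a3 by 0.59 ± 0.17. Against ND 1260 genes were higher and 1078 lower, and GC content correlated with the fold change at r = -0.373 across protein-coding genes. The count of 2338 became 112 without diet-switch libraries 3, 4 and 7. With the axis as a covariate, which can also remove part of the group difference, it became 36. Genes named here that passed in neither stood without those libraries, with fewer samples in the fit, at (adjusted p in brackets) Dgat2 -0.91 ± 0.28 (0.115), Mvd -1.06 ± 0.33 (0.106), Thbs1 1.54 ± 0.40 (0.0554) and Col6a3 0.66 ± 0.18 (0.0577), and with the axis at Dgat2 -0.55 ± 0.23 (0.381), Mvd -0.94 ± 0.32 (0.241), Thbs1 1.38 ± 0.48 (0.265) and Col6a3 0.68 ± 0.18 (0.113). The count was 1470 with only these 2 groups, and 1543, 1321 and 1475 without ND 4, diet switch 3 and diet switch 4.

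Direct tests compared the treatments. Doses and times are not in the labels, so whether the drugs were matched is unknown, and so is whether the switch followed a drug. Tirzepatide against semaglutide gave 649 higher and 935 lower genes. Lower with tirzepatide were Lep -1.10 ± 0.29 (log2, SE, n = 8 per group), Sfrp5 -1.49 ± 0.39, Nos2 -1.87 ± 0.45 and Igfbp3 -2.15 ± 0.30, a carrier of insulin-like growth factors. Slc2a4 was higher by 0.94 ± 0.15, above the semaglutide median in 8 of 8 libraries (edgeR adjusted p = 1.71e-04), and Acacb, an acetyl-CoA carboxylase, by 1.27 ± 0.23. Of the 23 fixed marker genes tested, 18 did not pass; for Adipoq the 95% interval of the difference was -0.33 to 0.343 and for Scd1 -0.219 to 0.565, while for Fasn it was 0.338 to 1.67 (adjusted p = 0.0513). Fasn passes on leaving out any one of semaglutide 8, tirzepatide 4, 6 and 7, and diet switch 3, 4, 5 and 8. In the expansion list, of the 7 measured, 3 fell and 4 did not pass; 5 fell adjusted over the list alone, and camera's adjusted p was 0.951 with an estimated correlation. In the B cell list, of the 5 measured, 3 fell and 2 did not pass; 5 fell adjusted over the list alone, and camera's adjusted p was 0.768 with an estimated correlation. In the muscle list, of the 14 measured, 3 rose and 11 did not pass; 14 rose adjusted over the list alone, and camera's adjusted p was 0.768 with an estimated correlation. The count of 1584 fell to 959 without the B-cell-high libraries and to 225 without the muscle-high ones, where with fewer samples Lep -0.88 ± 0.44 (0.318), Sfrp5 -1.91 ± 0.59 (0.103) and Nos2 -1.22 ± 0.55 (0.263) did not pass (adjusted p in brackets).

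Semaglutide against the diet switch gave 994 higher and 1107 lower genes. Enzymes of lipogenesis among the lower were Fasn -2.67 ± 0.36, Acly -2.41 ± 0.34, Acaca -2.23 ± 0.27 and Scd1 -1.36 ± 0.20. In that list, of the 25 measured, 11 fell and 14 did not pass; 14 fell adjusted over the list alone, and camera's adjusted p was 0.539 with an estimated correlation. In the expansion list, of the 7 measured, 3 rose and 4 did not pass; 5 rose adjusted over the list alone, and camera's adjusted p was 0.672 with an estimated correlation, with Mest 1.68 ± 0.47, Sfrp5 1.37 ± 0.39 and Lep 1.07 ± 0.29. In the T and NK cell list, of the 12 measured, 5 rose and 7 did not pass; 7 rose adjusted over the list alone, and camera's adjusted p was 0.672 with an estimated correlation, beside the B and T cell levels of semaglutide libraries 1, 3 and 8. The count of 2101 became 1230 without the B-cell-high libraries, 276 without diet switch 3, 4 and 7, and 504 with the axis as a covariate. Without diet switch 3, 4 and 7, with fewer samples in the fit, Lep 1.07 ± 0.34 (0.0953), Mest 1.93 ± 0.55 (0.0622) and Sfrp5 1.56 ± 0.44 (0.0594) did not pass (adjusted p in brackets), nor did Mest 1.76 ± 0.52 (0.0536) with the covariate or Lep 1.10 ± 0.37 (0.0591) without muscle-high libraries. The count was 1213 with only these 2 groups, where Mest 1.67 ± 0.52 (0.0535) and Sfrp5 1.36 ± 0.43 (0.0563) did not pass, and 1367 and 1371 without diet switch 3 and 7.

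Tirzepatide against the diet switch gave 18 higher and 45 lower genes. Lower ones included Elovl6 -2.57 ± 0.43, Acly -2.26 ± 0.34, Acss2 -1.91 ± 0.31, Fasn -1.67 ± 0.35 and Scd1 -1.18 ± 0.20, and the collagens Col3a1 -0.85 ± 0.17, Col4a1 -0.78 ± 0.16 and Col6a3 -0.79 ± 0.17; the growth factor Mdk was higher by 1.36 ± 0.24. In the lipogenesis list, of the 25 measured, 9 fell and 16 did not pass; 10 fell adjusted over the list alone, and camera's adjusted p was 0.339 with an estimated correlation. With only these 2 groups in the fit 1 gene passed, Mdk. There Acly -2.25 ± 0.48 (0.151), Elovl6 -2.57 ± 0.55 (0.151), Fasn -1.66 ± 0.45 (0.250) and Scd1 -1.18 ± 0.22 (0.113) did not pass (adjusted p in brackets), at about the size given above. Without muscle-high libraries 1 gene passed as well, but this was Acly at -2.77, and Mdk 1.11 ± 0.35 (0.817), Col3a1 -1.06 ± 0.26 (0.406), Col4a1 -0.57 ± 0.26 (1.00) and Col6a3 -0.95 ± 0.25 (0.412) did not pass. GC content correlated with the fold change at r = 0.336 across protein-coding genes, and after the correction for GC content and length 80 genes passed. The count of 63 compares with 238 with DESeq2, 120 with limma-voom weights, 99 with a replicate block, 123 without B-cell-high libraries and 347 without diet switch 3, 4 and 7. Leaving out tirzepatide 3, 5 or 8 or diet switch 2 gave 35, 135, 357 and 133.

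The 712 HFD genes were then sorted by what became of them. A gene counted as restored or partly restored when it passed against HFD in the opposite direction and did not lie past ND. That held for 223 genes (31.3%) with semaglutide, 402 (56.5%) with tirzepatide and 428 (60.1%) after the diet switch. Of the 447 genes raised by HFD the numbers were 166, 270 and 270, and of the 265 lowered ones 57, 132 and 158. All 17 Mup genes, the uncertain near copies named above, count among the 158. With either drug 0 of them were called above HFD, so they add to the lead of the switch in lowered genes. Genes away from ND in the HFD direction with no call back toward it numbered 137, 123 and 112, to which 7, 18 and 15 partly restored ones add. Those past ND on the other side numbered 1, 35 and 32, and undecided ones 351, 152 and 140. All 3 treatments restored 102 raised and 34 lowered genes at least partly, and 95 raised and 64 lowered genes were restored or partly restored by none. Oxtr, Ubd and Cfd moved back with each treatment, and Lep, Mest and Sfrp5 with tirzepatide and the switch. Groups simulated at the HFD level gave 0.00394% restored, and groups simulated at the ND level 61.8%, so full return there still left many genes undecided. These simulations called 1691 and 1681 genes on HFD in place of 712, so their shares cannot be set against the real ones. Without the muscle-high libraries, which include 2 of ND and 1 of HFD, 531 genes were called on HFD, and 172 of them were restored or partly restored with semaglutide, 206 with tirzepatide and 295 after the switch.

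**Figure D4:**
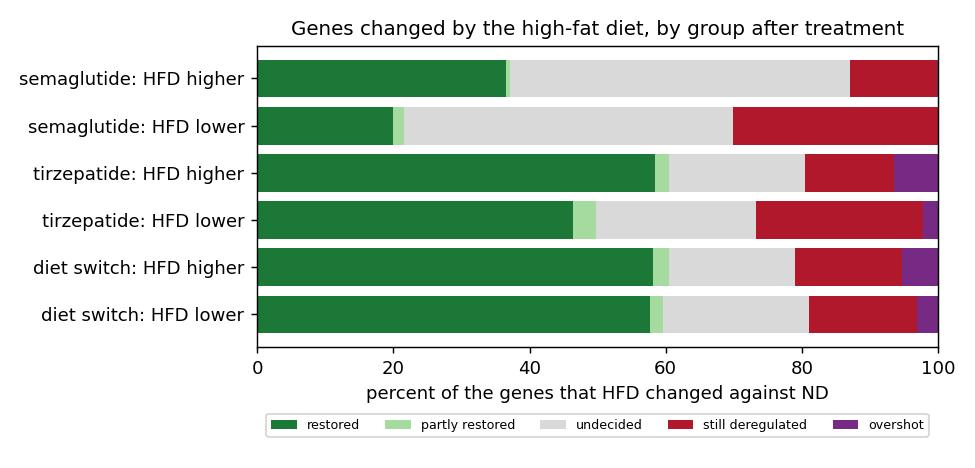
Stacked bars give the percent of the 712 HFD genes in each class for the 3 treatments, separately for genes raised and lowered by HFD. Of all of them semaglutide has 351 undecided genes, against 152 with tirzepatide and 140 after the switch.

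A recovery share measured how far the HFD profile moved back to ND, with genes chosen in libraries of odd or even number (91 and 132 genes) and measured in the others. It was 50.6% with semaglutide (95% bootstrap interval 38.4 to 67.8), 70.5% with tirzepatide (63.9 to 81.4) and 81.1% after the switch (72.9 to 96.3). Per library it averaged 52.3% ± 21.7 (SD, n = 8), 73.3% ± 7.09 and 83.1% ± 12.7. By an exact two-sided permutation test over 12870 assignments semaglutide lay below tirzepatide (difference -21 points, p = 0.016, adjusted 0.024) and below the switch (-30.8, p = 0.0014, adjusted 0.0042), while tirzepatide and the switch differed by -9.85 (p = 0.0741, adjusted 0.0741). The 95% bootstrap interval of this last difference, taken on the shares, was -22 to -1.45, with the switch above tirzepatide throughout. It parts there from the permutation test. For genes raised by HFD the shares were 64.4%, 76.7% and 77.9%, and for lowered genes 32%, 59.3% and 91%. Shares without the Mup genes were not taken. Skeletal muscle levels, given above, were also lower in HFD and with semaglutide than in the other groups, and Myh1 is among the HFD-lowered genes. In tests chosen after seeing the data, the shares without 92 genes that follow the muscle score within groups were 52.0%, 71.8% and 81.8%. For raised genes these were 65.1%, 78.5% and 79.1%, and for lowered ones 32.3%, 58% and 89.2%. Without the muscle-high libraries, with 3 libraries of tirzepatide and 5 of the switch left, the shares over both directions were 48.1%, 81.4% and 75.7%, with tirzepatide above the switch. With all libraries, each of the 35 ways to halve the replicate numbers put semaglutide lowest and the switch highest, with means of 54.3%, 76.2% and 88%. These halvings reuse the same libraries, so they are not independent and do not settle the order of tirzepatide and the switch. With replicates 1 to 4 against 5 to 8 the share was 97.7% for tirzepatide and 122% for the switch.

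**Figure D5:**
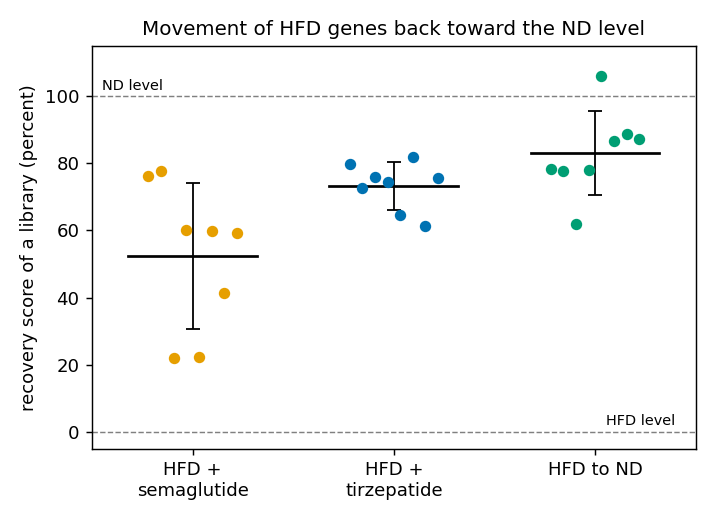
Points give the recovery share of each library in percent (0 is the HFD level, 100 the ND level), n = 8 per treatment, with mean and SD. Semaglutide libraries spread from 22.1 to 77.6, tirzepatide from 61.2 to 81.9 and the diet switch from 61.8 to 106.

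Fold changes against HFD were compared between treatments across 15807 genes, which are not independent replicates. Pearson's r was 0.523 for semaglutide and tirzepatide, 0.468 for semaglutide and the switch, and 0.819 for tirzepatide and the switch. Unchanged groups, simulated with HFD libraries that were simulated too and shared between the comparisons, gave 0.502, 0.501 and 0.502. The covariances were 0.171, 0.154 and 0.355, against simulated 0.0527, 0.0525 and 0.0528. With the HFD libraries split between the comparisons r was 0.369, 0.322 and 0.672, where the simulations with the same split gave 0.00723, 0.00618 and 0.00769. Semaglutide and tirzepatide shared 145 raised and 303 lowered genes, semaglutide and the switch 143 and 294, and tirzepatide and the switch 1102 and 960. Independent lists of these sizes would share 23.6 and 44.6, 31 and 45.4, and 199 and 186. The real lists share the HFD libraries, which these expected numbers leave out. Groups simulated at the HFD level gave 0 genes called with both drugs in 1 direction. They had only 0.0667 calls against HFD on average, so this cannot tell how far shared libraries add to the overlap. All 3 shared 123 raised and 252 lowered genes.

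The main genes are placed on mm10 with GENCODE M21. Fasn lies on chromosome 11 from 120805846 to 120824547, Acly on chromosome 11 from 100476353 to 100528000, and Scd1 on chromosome 19 from 44394455 to 44407879. Lep lies on chromosome 6 from 29060220 to 29073877, Mest on chromosome 6 from 30723547 to 30748465, and Sfrp5 on chromosome 19 from 42197971 to 42202252. Slc2a4 lies on chromosome 11 from 69942539 to 69948188, and Per2 on chromosome 1 from 91415982 to 91459324.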

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

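The tests between treatments and the search for libraries far from their group were set before the data were examined. In all 338 sets of 8 values were searched, 32 held a library set apart from its 7 group mates by Dixon's test, and chance alone gives about 1 in 20, or 16.9.

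ND library 5 held 15 of the 32. Its B cell genes stood at 6.87 log2 CPM (others 1.35 to 2.83), T and NK cell genes at 4.98 (0.521 to 1.83), MHC class II genes at 7.06 (5.45 to 6.15), lymphatic endothelium at 4.50 (1.92 to 3.14) and cell cycle genes at 2.91 (1.37 to 1.96). Adipose lists in which it was the lowest of ND were the expansion list at 4.53 (6.38 to 7.11), adipokines at 6.55 (7.07 to 7.32), creatine and calcium cycling at 2.79 (3.63 to 4.17) and matrix at 6.21 (6.82 to 7.22). Some single genes were the lowest as well, though Fasn, Acly and Scd1 were not, with Lep at 7.20 (9.27 to 10.1), Pparg at 6.17 (6.84 to 7.30), Sfrp5 at 4.55 (6.40 to 7.44), Npr3 at 5.55 (7.92 to 9.10), Pnpla2 at 10.4 (11 to 11.5) and Col6a3 at 7.40 (7.99 to 8.42). Without this library 853 genes in place of 417 were called between semaglutide and ND.

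Further libraries apart from their group were ND 6 with Ucp1 at 5.44 log2 CPM (others -0.947 to 1.31) and HFD 4 with muscle genes at 5.61 (1.39 to 2.38). Semaglutide 1 was low for matrix genes at 6.23 (6.70 to 7.08), Scd1 at 11 (12 to 12.6) and Mest at 1.24 (4.41 to 6.06). Semaglutide 8 was high for thermogenic genes at 4.14 (3.19 to 3.62) and Ucp1 at 3.57 (-0.947 to 0.257), and semaglutide 7 for immediate early genes at 4.70 (3.72 to 4.12). Semaglutide 3 had 14.8% mitochondrial counts (9.16 to 11.6) and keratinocyte genes at 1.27 (2.38 to 3.36). Tirzepatide 1 had 12.7% of counts on 18S RNA (4.82 to 8.13) and Acly at 8.17 (6.04 to 6.95), and HFD 3 had 5.41% on 18S RNA (7.21 to 8.81). Tirzepatide 8 was low for smooth muscle genes at 4.43 (5.00 to 5.47) and tirzepatide 3 for hypoxia genes at 4.71 (5.05 to 5.34). Diet switch 6 was high for creatine and calcium cycling at 4.23 (3.89 to 4.05), and diet switch 4 for T and NK cell genes at 2.88 (0.684 to 1.65).

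Treatments differed by direct edgeR tests. Tirzepatide against semaglutide gave 1584 genes, semaglutide against the diet switch 2101, and tirzepatide against the diet switch 63. Between the drugs Lep (-1.10), Pparg (-0.97), Sfrp5 (-1.49) and Ccl2 (-1.54) were lower with tirzepatide and Slc2a4 (0.94) was higher. The Pparg call ends without tirzepatide 3 or 4 (highest edgeR adjusted p 0.0533), and the Ccl2 call without semaglutide 2, 5 or 7 or tirzepatide 1, 2, 3 or 4 (highest 0.0775). Without muscle-high libraries Pparg stood at -0.34 ± 0.32 (adjusted p = 0.644), and Ccl2 -1.32 ± 0.52 (0.193), Lep -0.88 ± 0.44 (0.318) and Sfrp5 -1.91 ± 0.59 (0.103) did not pass. Pparg -0.96 ± 0.30 (0.0587) and Ccl2 -1.54 ± 0.50 (0.0708) did not pass without the filter, nor did Pparg -0.94 ± 0.32 (0.0694) and Ccl2 -1.40 ± 0.51 (0.0862) with the axis of variation as a covariate or Pparg -0.97 ± 0.36 (0.0990) with only the groups compared. With semaglutide against the switch Fasn (-2.67), Acly (-2.41), Scd1 (-1.36), Slc2a4 (-0.76) and Col6a3 (-0.62) were lower, and Mest (1.68), Sfrp5 (1.37), Lep (1.07) and Itgax (1.07) higher. Without diet switch 3, 4 and 7, with fewer samples in the fit, Mest 1.93 ± 0.55 (0.0622), Sfrp5 1.56 ± 0.44 (0.0594) and Lep 1.07 ± 0.34 (0.0953) were not called, though not smaller. With tirzepatide against the switch Acly (-2.26), Fasn (-1.67), Scd1 (-1.18) and Col6a3 (-0.79) were lower. With only these 2 groups in the fit they were not called, at Acly -2.25 ± 0.48 (0.151), Fasn -1.66 ± 0.45 (0.250), Scd1 -1.18 ± 0.22 (0.113) and Col6a3 -0.78 ± 0.19 (0.151). The recovery share with semaglutide lay -21 points from tirzepatide and -30.8 points from the switch.

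Splits of the 16 libraries of a comparison show whether chance can be excluded. It can for HFD against ND, with 712 genes against at most 16 in the other of 100 splits, for semaglutide against HFD (656; 12), tirzepatide against HFD (3246; 1065) and the switch against HFD (3759; 744). It can also for semaglutide (417; 346), tirzepatide (1591; 271) and the switch (2338; 1221) against ND, for tirzepatide against semaglutide (1584; 72) and for semaglutide against the switch (2101; 1976). In these 9 comparisons only 1 of 100 splits, the real one, gave as many genes; the split with 1976 moved 1 library of each group to the other side. The splits with 346, 271 and 744 left only 5 of 8 libraries on their own side, and those with 1065 and 1221 left 6. Such splits keep part of the treatment difference, so their counts do not tell whether another structure of the samples adds to it. For semaglutide against ND the split with 346 comes near the real count, which itself falls to 256, 264 and 272 without ND 4, ND 1 and semaglutide 3, so that exclusion is weak. Real counts also fall under the highest other split for semaglutide against the switch, to 1367 without diet switch 3. For the switch against ND the count falls to 112 without diet switch 3, 4 and 7. Those exclusions are weak too. For tirzepatide against the switch 5 of 100 splits gave as many as the real 63, the highest 282, so chance cannot be excluded, and a split with several times the real count points to a structure of the samples other than treatment.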

How the results depend on the processing

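Counts were taken as kept within 1.5 times, recovery shares within the SD of their library scores, and r within its SE from single libraries left out. Only shares and r could change direction, and 0 did. Of 120 values under alternatives fixed before the data were examined, 100 were kept and 20 moved. Of 94 under alternatives chosen after seeing the data, 75 were kept and 19 moved. The cause was not tested, except that settings without libraries fit fewer samples by construction. Limma-voom weights gave 1289 genes for HFD against ND, 1263 for semaglutide against HFD, 952 and 2451 for semaglutide and tirzepatide against ND, and 120 for tirzepatide against the switch. DESeq2 gave 1023 for semaglutide against HFD and 238 for tirzepatide against the switch. With only the groups compared the counts were 1013 for semaglutide against HFD, 1470 for the switch against ND, 1213 for semaglutide against the switch and 1 for tirzepatide against the switch. Without the filter semaglutide against ND had 267. List tests passing numbered 76 with a preset correlation and 57 with fry, against 4 of 360. With replicates 1 to 4 against 5 to 8 the recovery share was 97.7% for tirzepatide and 122% for the switch. The r with the HFD libraries split was 0.369, 0.322 and 0.672. Sharing no HFD libraries lowers r by construction, and simulated r there was 0.00723, 0.00618 and 0.00769.

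Among alternatives chosen after seeing the data, leaving out the B-cell-high libraries gave 412 genes for semaglutide against HFD, 959 for tirzepatide against semaglutide, 1230 for semaglutide against the switch and 123 for tirzepatide against the switch. Leaving out the muscle-high libraries gave 1145 and 332 for tirzepatide against HFD and ND, 225 against semaglutide, 1 against the switch, 206 of 531 HFD genes restored or partly restored with tirzepatide, and a recovery share of 81.4% with tirzepatide. Without diet switch 3, 4 and 7 the counts were 1148 against HFD, 112 against ND, 276 for semaglutide and 347 for tirzepatide against the switch. With the axis of variation as a covariate they were 1885 and 448 for tirzepatide against HFD and ND, 801 and 36 for the switch, and 504 for semaglutide against the switch. Since the groups' means differ on the axis, these falls may include part of the treatment difference.

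The replicate number as a block gave 761 genes for HFD against ND, 635, 3487 and 3930 for semaglutide, tirzepatide and the switch against HFD, 425, 1810 and 2492 against ND, and 1715, 2194 and 99 for the direct comparisons. Of 80 pairs of libraries with the same number in 2 groups, 21 correlated above 0.1 over 2000 genes and 14 correlated best with their own number. Mean r of the same number ran from -0.0355 to 0.0774 between groups. The numbers thus give no clear pairing, though a weak shared factor is not excluded.

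Leaving out single libraries gave 541 to 778 genes for HFD against ND, 437 to 895, 2529 to 3442 and 2849 to 4312 for semaglutide, tirzepatide and the switch against HFD, 256 to 853, 1046 to 1797 and 1321 to 3075 against ND, and 1087 to 1778, 1367 to 2797 and 35 to 357 for the direct comparisons. Of 2063 values of named genes under the alternatives other than single libraries, 1957 counted as kept, 92 no longer passed and 14 passed only under the alternative. Among genes called in the main fit 0 values changed direction. For genes not called there a change of sign counted as kept.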

Other observations

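The tests of the 3 patterns below were all chosen after seeing the results they measure. Some genes of blood vessels and the respiratory chain were called, while their list tests did not pass. On HFD Cdh5, a junction protein of vessels, rose by 0.63 ± 0.15 (log2, SE, n = 8 per group), and in the vascular list, of the 14 measured, 3 rose and 11 did not pass; 4 rose adjusted over the list alone, and camera's adjusted p was 0.151 with an estimated correlation. After the diet switch Aplnr, the apelin receptor, fell by 1.14 ± 0.28 against HFD, Eng, a coreceptor of growth factors, stood at -0.70 ± 0.20 and the adhesion molecule Pecam1 at -0.66 ± 0.17; in that list, of the 14 measured, 1 rose, 5 fell and 8 did not pass; 1 rose and 7 fell adjusted over the list alone, and camera's adjusted p was 0.757 with an estimated correlation. Without diet switch 3, 4 and 7 they did not pass (adjusted p in brackets): Aplnr -0.77 ± 0.27 (0.0799), Eng -0.48 ± 0.22 (0.180) and Pecam1 -0.56 ± 0.20 (0.0780), nor with the axis of variation as a covariate: Aplnr -0.71 ± 0.27 (0.127), Eng -0.24 ± 0.18 (0.497) and Pecam1 -0.49 ± 0.19 (0.122). The Eng call also ended without the muscle-high libraries, at -0.68 ± 0.25 (0.0553). With tirzepatide against ND Uqcrfs1, Sdhc and Ndufs3, subunits of the respiratory chain, stood at -0.98 ± 0.24, -0.85 ± 0.19 and -0.65 ± 0.14, and in the oxidative phosphorylation list, of the 36 measured, 8 fell and 28 did not pass; 12 fell adjusted over the list alone, and camera's adjusted p was 0.844 with an estimated correlation. Without the muscle-high libraries Uqcrfs1 -0.70 ± 0.31 (0.218) and Sdhc -0.42 ± 0.24 (0.371) did not pass, nor with the axis as a covariate Uqcrfs1 -0.55 ± 0.22 (0.185) and Sdhc -0.64 ± 0.19 (0.0613). In the thermogenic list for HFD against ND, of the 15 measured, 5 rose and 10 did not pass; 7 rose and 4 fell adjusted over the list alone, and camera's adjusted p was 0.630 with an estimated correlation, with Dio2 2.06 ± 0.50 and Clstn3 1.72 ± 0.31; its median was -0.347 and its mean -0.0278 while camera's direction was up.

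Cdkn1a, an inhibitor of the cell cycle, fell with each treatment against HFD: -1.66 ± 0.23 with semaglutide, -2.20 ± 0.23 with tirzepatide and -2.03 ± 0.23 after the switch (log2, SE, n = 8 per group). It lay under ND too (-1.25 ± 0.23, -1.79 ± 0.23 and -1.62 ± 0.23). Of the genes lowered by HFD, 38 stayed below ND with both drugs and not after the switch, and 15 in all 3. Of the 38, 16 are Mup genes, 1 is a Mup pseudogene and 21 are other genes, while the 15 hold 0 Mup genes. Of those raised, 5 and 22 stayed above. These comparisons share the ND libraries. The Mup genes, uncertain as a family of near copies, were below ND with semaglutide (17 of 17, -4.91 to -4.43) and tirzepatide (16 of 17, -2.11 to -1.69) and above semaglutide with tirzepatide (17 of 17, 2.45 to 3.04).

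Lipogenesis genes lay below ND with either drug (18 of 25 each). A lower share of adipocytes is argued against as the whole source. Adipocyte identity genes exceeded lipogenesis genes by a change of at least 1.35 against ND (1.35 ± 0.166 and 1.36 ± 0.185, SE). The identity score itself lay -0.00745 ± 0.152 from ND with semaglutide and 0.0818 ± 0.16 with tirzepatide (SE). Members such as Cfd and Slc2a4 changed between groups, so this score does not measure the share of adipocytes alone. Calls under the correction for GC content and length are given for semaglutide only. Such a trend over whole transcripts is argued against there as the whole source, since 16 of 18 calls stay. The 2 that end, named after their values were seen, were near the threshold before: Mlxipl went from -0.59 ± 0.17 (adjusted p = 0.0438) to -0.51 ± 0.17 (0.103) with semaglutide and Agpat2 went from -0.91 ± 0.24 (adjusted p = 0.0291) to -0.71 ± 0.24 (0.114) with semaglutide. The Mlxipl call also ends without any one of ND 1, 2, 3, 4 or 8 or semaglutide 1, 3, 4, 5, 6, 7 or 8 (highest adjusted p 0.138), and without the filter (0.0977), with only the groups compared (0.0765), with the replicate block (0.0631), without B-cell-high libraries (0.155) and without muscle-high libraries (0.164). The Agpat2 call also ends without any one of ND 2 or 4 or semaglutide 1, 2, 5, 6 or 7 (highest adjusted p 0.0689), and without the filter (0.0819). An action of the drugs as the whole source is argued against too, since the list score in HFD without a drug lay -0.944 from ND (SE 0.0948). It was 7.73 ± 0.229 log2 CPM in ND (SD, n = 8), 6.78 ± 0.139 in HFD, 6.36 ± 0.180 with semaglutide and 6.45 ± 0.379 with tirzepatide. Against HFD 6 members fell and 1 rose with semaglutide, 10 fell and 6 rose with tirzepatide, and neither list test passed, so a further action of the drugs stays open. The fat content of the diet at collection may take part, since 9 members were lower with tirzepatide than after the switch to ND and 11 with semaglutide, and 0 were higher. With only the tirzepatide and switch groups in the fit 1 gene in all was called. There Fasn stood at -1.66 ± 0.45 and Acly at -2.25 ± 0.48, in place of -1.67 ± 0.35 and -2.26 ± 0.34, so these calls ended with a wider SE at a like change. The labels give no food intake.

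The switch against ND gave 2338 genes, and 112 without libraries 3, 4 and 7. The other 55 sets of 3 switch libraries left out gave 166 to 4068 (median 1622), so these 3 libraries likely carry many of the calls. A trend with GC content and length of whole transcripts is argued against as the whole source, since 1715 genes pass after its correction. GC content of the counted ends was not corrected for. Levels against gene means correlated with GC content at r = -0.34, -0.265 and -0.293 in libraries 3, 4 and 7. In the other 5 r ran from -0.289 to 0.144. With the axis on which libraries 3, 4 and 7 stand apart as a covariate, far fewer genes pass, as given above. That covariate can also remove part of the group difference itself. In libraries 3, 4 and 7 18S RNA took 6.13, 5.5 and 5.65% of counts, against 3.56 to 5.19 in the other 5 switch libraries. What sets them apart, handling or biology, stays open.

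Clock genes differed from ND with both drugs. A GC trend over whole transcripts as the whole source is argued against, as 18 of 20 calls stay after its correction. The 2 that end, named after their values were seen, were near the threshold before: Bhlhe41 went from 0.80 ± 0.22 (adjusted p = 0.0395) to 0.71 ± 0.23 (0.0883) with semaglutide and Cry1 went from -0.92 ± 0.30 (adjusted p = 0.0434) to -0.85 ± 0.30 (0.0627) with tirzepatide. The Bhlhe41 call also ends without any one of ND 1, 2, 3, 5, 6, 7 or 8 or semaglutide 2, 3, 4 or 7 (highest adjusted p 0.102), and without the filter (0.0556), without B-cell-high libraries (0.184) and without muscle-high libraries (0.1). The Cry1 call also ends without any one of ND 2, 5, 6 or 8 or tirzepatide 1, 3, 6, 7 or 8 (highest adjusted p 0.106), and without the filter (0.0713), with only the groups compared (0.0609), without B-cell-high libraries (0.0540), without muscle-high libraries (0.202) and with the axis as a covariate (0.0716). The list test rose from camera's adjusted p of 0.0148 to 0.0321 with semaglutide and from 0.0469 to 0.107 with tirzepatide, which no longer passed. All 20 calls of the 2 drugs lie in the direction of a common shift of phase, and so do 11 of 11 of the switch, as collection at another time of day could give, and the labels give no time, so this cannot be told apart from an action of the treatments. Genes in phase with Per2 had medians of 0.444 in HFD, 1.30 with semaglutide, 1.41 with tirzepatide and 1.19 after the switch, and those against it -0.533, -1.26, -1.75 and -1.12.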
